A study of Homo sapiens with 4 samples.

How the data were processed

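The study concerns direct reprogramming of human BJ fibroblasts, an established line of neonatal foreskin fibroblasts, toward the blood lineage. Per the labels, cells received lentiviral vectors for 5 transcription factors (GATA2, GFI1B, FOS, STAT5A and REL) whose expression was switched on with 1 µg/mL doxycycline for 48 hours, after which the medium was changed to one for blood progenitors. The series lists 4 samples: 2 of reprogrammed fibroblasts, 1 of untransduced BJ fibroblasts and 1 of bone marrow cells. Expression values of these 4 samples were not analysed here. All values come from 1 table of the reprogramming time series with a line per cell. The names of its 6 samples match none of the 4 listed samples, so its columns were read as a table of the whole series and its cells were grouped only by the day label that the table itself gives each cell.

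The table holds 6250 cells, each with an identifier and a quality-filter flag. The 6172 cells that passed the filter also have a sample name, a day label, 2 cell cycle scores and a called cell cycle phase. The S score and the G2/M score are per-cell scores deposited by the authors. Per the submitters' processing notes, Scanpy was used with the genome build GRCh38. The gene lists behind the scores, the aligner, the counting, the normalization, the thresholds of the quality filter and the treatment of doublets are not given in the sources used here. A score of this kind compares a set of phase genes with control genes within a cell, so it has no unit and no true zero. Score levels are given as medians and percentiles per group and compared as differences, and no fold change of a score level was taken. The deposited phases equalled a rule on the scores in all 6172 cells that passed the filter: G1 where both scores were below 0, otherwise the phase with the higher score. A phase is therefore a range of a score and not a separate measurement. The 78 cells that failed the filter carried no sample name, day, score or phase.

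The labels' protocols describe droplet capture of single cells followed by nanopore sequencing. Each cell identifier in the table is made of 3 two-digit numbers, of which the first takes 12 values and each of the others 96 values. Identifiers of this form differ from the nucleotide barcodes of droplet capture, and whether the described protocol was used for the time series is not stated, so the cells may have been barcoded in another way. Each first number occurred with only 1 sample name. Cells sharing a first number are called a portion here. The untransduced cells came under 2 sample names of 1 portion each, day 0 under 1 sample name of 1 portion, and days 7, 14 and 21 under 1 sample name of 3 portions each. What the 3 numbers stand for is not given in the sources used here, and nothing says that portions, or both untransduced samples, came from separate cultures. Cells that failed the filter were placed by their first number.

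Cells were counted per group and phase in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and plots were drawn with matplotlib 3.10.9. Shares are of the cells that passed the filter, with exact Clopper-Pearson 95% intervals; differences of shares have Newcombe 95% intervals. Both cover counting error only and do not measure how far a repeat culture would differ. Tested on simulated data with the cell numbers and shares of each group, between 94.3% and 95.7% of 1000 Clopper-Pearson intervals per group held the true share. The simulated share was that called S or G2/M, drawn from independent cells as the intervals assume. It checks the calculation and not whether that assumption holds. No test between days was made, since each day was 1 sample and cells are not replicates. For 2 untransduced samples against 1 sample of a day, the smallest two-sided exact permutation p is 0.333. The spread over portions is given beside the differences as a technical spread. The number of reads behind each cell is unknown here, so phases and scores were not matched on depth.

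The plan, fixed before the data were examined, named the days, the phases and scores as results, and the genes to be named as those with a column of their own, of which the table has none. No marker list was therefore used. Planned summaries of totals, detected genes, mitochondrial and ribosomal percentages, clusters, signature scores and gene levels were not made for the same reason. The alternative settings named beforehand that could be run were the mean in place of the median score and leaving out each untransduced sample. Added after seeing the data were a cut of 0.1 in place of 0 on both scores, counting day 0 among the controls as 1 column of the table does, leaving out or equally weighting portions, and including the cells that failed the filter.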

Results

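The time series held 6172 cells that passed the authors' quality filter. Of these, 881 were untransduced BJ fibroblasts under 2 sample names (470 and 411 cells), 459 were labelled day 0, 1529 day 7, 1974 day 14 and 1329 day 21. The day 0 sample is named as a control with the suffix TD, and the series describes days 0, 7, 14 and 21 as collections of cells induced with the 5 factors. Whether the day 0 cells had been transduced, and whether they had received doxycycline, is not stated for this sample, so its values are those of the sample labelled day 0. Each cell had an S score, which summarises genes of DNA replication, a G2/M score, which summarises genes of the approach to and passage through mitosis, and a phase called from both. The comparisons asked how the cell cycle profile of the cultures differed between untransduced fibroblasts and each day of reprogramming. Each day was 1 sample, so the intervals below are counting error only and no difference between days carries a test.

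Untransduced fibroblasts had the highest share of cells called S or G2/M. Of 881 cells, 469 or 53.2% (exact 95% interval 49.9 to 56.6%) were called S or G2/M, with 35.6% called G2/M (32.5 to 38.9%) and 17.6% called S (15.1 to 20.3%). The remaining 46.8% were called G1, the phase before DNA replication. Every cell with both scores below 0 received this call, so the call does not by itself place a cell in that phase. Both untransduced samples gave similar shares: 54.9% (50.3 to 59.5%) and 51.3% (46.4 to 56.3%) called S or G2/M, and 35.1% and 36.3% called G2/M. Their S shares were 19.8% (16.3 to 23.7%) and 15.1% (11.8 to 18.9%).

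At day 0 most cells were called G1. The G1 share was 85.8% (82.3 to 88.9%) of 459 cells, against 46.8% of untransduced cells. The G2/M share was 3.49% (16 cells, 2.01 to 5.60%), which was 10.2-fold lower than in untransduced cells (13.1-fold with a cut of 0.1). The S share was 10.7% (8.00 to 13.9%), which was 1.65-fold lower with the deposited calls and 5.52-fold lower with a cut of 0.1 on both scores (2.18% against 12.0%). Together 14.2% of day 0 cells (11.1 to 17.7%) were called S or G2/M, a difference of -39.1 percentage points from untransduced cells (Newcombe 95% interval -43.4 to -34.3). The gap between the untransduced samples was 3.56 points.

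At day 7 the G2/M share was again high. It was 31.5% of 1529 cells (29.2 to 33.9%), 9.04-fold above day 0, with a difference of 28.0 percentage points (24.9 to 30.8). The S share was 13.8% (12.1 to 15.6%), and its difference from day 0 of 3.12 points had an interval that included 0 (-0.434 to 6.22), whereas with a cut of 0.1 the difference was 3.64 points (1.56 to 5.27). The share called S or G2/M was 45.3% (42.8 to 47.9%), against 14.2% at day 0. The 3 portions of day 7 gave 48.9%, 45.0% and 42.2%, an SD of 3.35 points where counting error alone gives 2.21. At days 14 and 21 this SD was below counting error (0.992 against 1.44 and 0.972 against 2.35 points). For the 2 untransduced portions it was 2.51 against 2.38 points. Compared with untransduced cells, the day 7 share called S or G2/M differed by -7.91 points (-12.0 to -3.77), and the G2/M share by -4.12 points (-8.06 to -0.218). These differences became -12.6 points (-16.7 to -8.59) and -6.44 points (-10.3 to -2.61) with a cut of 0.1.

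At day 14 the profile was again mostly G1. The G1 share was 83.8% of 1974 cells (82.1 to 85.4%), and the G2/M share was 3.50% (69 cells, 2.73 to 4.40%), 9.02-fold below day 7. Of these 69 cells, 39 had a G2/M score of at most 0.1, and with a cut of 0.1 the G2/M share was 18.2-fold below day 7. The S share of 12.7% (11.2 to 14.2%) differed from that of day 7 by -1.14 points, with an interval that included 0 (-3.43 to 1.11). With a cut of 0.1 this difference was -4.20 points (-5.57 to -2.95), since 87.2% of the S calls at day 14 had a score of at most 0.1. The share called S or G2/M was 16.2% (14.6 to 17.9%), and the 3 portions gave 16.4%, 16.9% and 15.02%. Its difference from day 0 was 2.00 points (-1.82 to 5.35), and the G2/M share differed from that of day 0 by 0.00960 points (-2.21 to 1.62). With a cut of 0.1 both differences were negative, at -1.65 points (-4.11 to 0.173) and -1.09 points (-3.05 to 0.190), with intervals that again included 0.

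At day 21 the share called G2/M was 26.0% of 1329 cells (23.7 to 28.5%), 7.45-fold above day 14 (12.9-fold with a cut of 0.1). The S share was 15.7% (13.8 to 17.8%), 3.06 points above day 14 (0.648 to 5.55). The share called S or G2/M was 41.8% (39.1 to 44.5%), with 42.1%, 42.4% and 40.6% in the 3 portions. Against day 7 the G2/M share differed by -5.49 points (-8.79 to -2.16), while the difference in the share called S or G2/M of -3.56 points had an interval that included 0 (-7.19 to 0.0824). These differences became -8.09 points (-11.2 to -4.97) and -9.55 points (-12.8 to -6.23) with a cut of 0.1. Against untransduced cells, the share called S or G2/M differed by -11.5 points (-15.7 to -7.23), the G2/M share by -9.61 points (-13.6 to -5.68) and the S share by -1.87 points (-5.11 to 1.27). Raising the cut to 0.1 made the first of these -22.2 points (-26.2 to -18.2) and the G2/M difference -14.5 points (-18.3 to -10.7). The S difference depended on the settings: it was 0.641 points without the untransduced sample of 470 cells, -4.06 points without that of 411, and -7.67 points (-10.2 to -5.33) with a cut of 0.1.

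**Figure D1:**
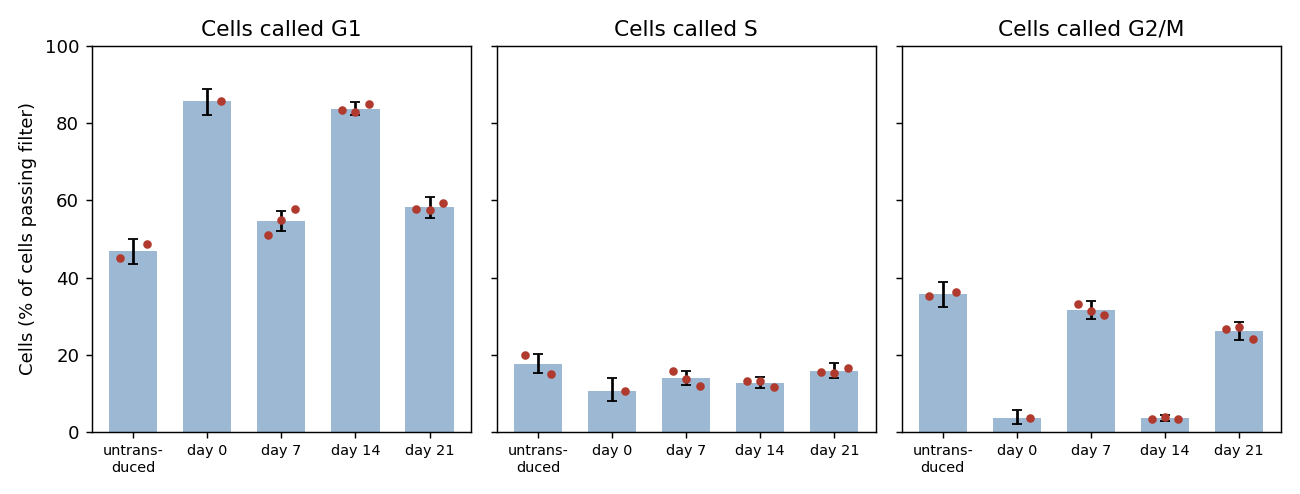
Share of cells called G1, S and G2/M (percent of cells passing the filter) in untransduced fibroblasts and at days 0, 7, 14 and 21; bars are all cells of a group, error bars exact 95% intervals (counting error only), and points the single portions. The G2/M share was 3.49% at day 0 and 3.50% at day 14, against 35.6% in untransduced cells, 31.5% at day 7 and 26.0% at day 21, while S shares lay between 10.7% and 17.6%.

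The share called S or G2/M at day 14 lay 25.6 percentage points below that of day 21, the nearer of the high days, and the largest range over the portions of 1 day was 6.68 points. The low share of day 14 was thus separated from days 7 and 21 by more than the spread over portions. Day 0, which lay 27.6 points below day 21, had 1 portion, so its own technical spread was not measured. Whether these gaps exceed the spread between cultures cannot be tested with 1 sample per day.

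At their upper end, the scores behind the calls followed the order of the G2/M share and of the share called S or G2/M. The calls are cuts on these same scores, so this agreement is largely set in advance and is no separate evidence. Days 0 and 14 had nearly equal G2/M shares, whose order changed with a cut of 0.1. The 90th percentile of the G2/M score was 0.917 in untransduced cells, -0.050 at day 0, 0.676 at day 7, -0.033 at day 14 and 0.475 at day 21. For the S score it was 0.424, 0.0081, 0.227, 0.013 and 0.151 in the same order. Day 21 thus lay below day 7 in this S score percentile, although its S share with the deposited calls was 15.7% against 13.8%. That S share difference of 1.93 points had an interval that included 0 (-0.675 to 4.55). With a cut of 0.1 it was -1.46 points (-3.07 to 0.176), so which day had the higher S share is not settled. Median S scores were 0.0099 in untransduced cells, -0.062 at day 0, -0.031 at day 7, -0.059 at day 14 and -0.034 at day 21. The median G2/M scores of untransduced and day 7 cells were both close to -0.069 (quartiles -0.143 to 0.597 and -0.131 to 0.217), and those of days 0, 14 and 21 were -0.13, -0.12 and -0.095. Cells called G2/M also differed in how high they scored. Their median G2/M score was 0.718 in 314 untransduced cells, 0.393 in 16 cells at day 0, 0.479 in 482 cells at day 7, 0.045 in 69 cells at day 14 and 0.315 in 346 cells at day 21.

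Many calls lay near the cut. In 2169 cells (35.1%) the higher of both scores was within 0.05 of 0, from 19.5% of untransduced cells to 43.8% of day 14 cells. With a cut of 0.1 on both scores, the S share was 12.0% in untransduced cells, 2.18% at day 0, 5.82% at day 7, 1.62% at day 14 and 4.36% at day 21. The S gap between untransduced and day 14 cells was thus wider than with the deposited calls (17.6% and 12.7%), while the small difference between days 0 and 14 changed direction, with an interval that included 0 (-0.558 points for day 14 minus day 0, -2.40 to 0.632). The G2/M shares with this cut were 34.2%, 2.61%, 27.7%, 1.52% and 19.6% in the same order. One column of the table counts day 0 among the controls. With that control, 39.9% of control cells were called S or G2/M, and the differences of day 7 and day 21 from control changed direction to 5.47 and 1.91 percentage points.

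**Figure D2:**
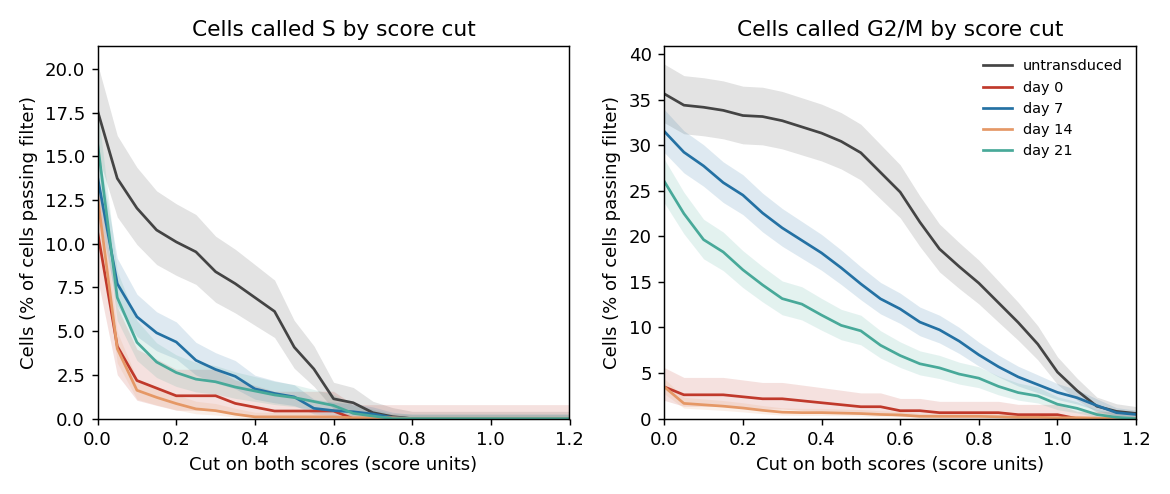
Share of cells called S (left) and G2/M (right), in percent of cells passing the filter, as the cut on both scores is raised from 0 to 1.2 score units; lines are the 5 groups and bands exact 95% intervals (counting error only). S shares run from 10.7% to 17.6% at a cut of 0 and from 1.62% (day 14) to 12.0% (untransduced cells) at a cut of 0.1. G2/M shares of days 0 and 14 are 3.49% and 3.50% at a cut of 0, and 2.61% and 1.52% at a cut of 0.1.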

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

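All tests in this part were chosen after the result was seen. Cells that failed the quality filter were absent among untransduced cells and were listed on each of the days. None of 881 untransduced cells failed, which allows a share of up to 0.341% by a limit of 3 counts, or 0.418% by the exact 95% interval. The share was 1.08% at day 0 (5 of 464 cells, exact 95% interval 0.351 to 2.497%), 1.48% at day 7 (23 of 1552, 0.942 to 2.22%) and 2.13% at day 14 (43 of 2017, 1.55 to 2.86%). It was 0.524% at day 21 (7 of 1336, 0.211 to 1.08%), and without the portion that held 5 of these cells it was 0.216% (2 of 927). The day 21 interval reaches below both limits set by the untransduced cells, and the day 0 interval below the exact one. Within day 14 the 3 portions differed: 0.578% (4 of 692), 3.47% (24 of 691) and 2.37% (15 of 634).

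A faulty second or last number of the identifier as the source is argued against by the 54 distinct last numbers and 54 distinct second numbers among the 78 failed cells. Assigning the failure to cells at random gave 48 to 59 distinct last numbers and 47 to 58 distinct second numbers (95% range of 10000 shuffles). Thresholds of the filter set separately per sample, a lower quality of the collected cells on those days, or removed doublets stay open, since the failed cells carry no scores and the thresholds are not given in the sources used here. A per-sample threshold or a day-wide quality would act alike on all portions of day 14. Neither alone accounts for the gap between its portions with 0.578% (0.158 to 1.47%) and 3.47% (2.24 to 5.12%). A source that acts on single portions also stays open and was not tested. The failed cells were too few to move the cell totals: the day 14 total is 2017 with them and 1974 without.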

How the results depend on the processing

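The share called S or G2/M was lower at days 0 and 14 than in untransduced cells and at days 7 and 21 under each alternative that gives shares (the cut of 0.1, equal weights for portions, and leaving out portions or an untransduced sample); day 14 was also lower than a control that includes day 0. All alternatives except the mean score and leaving out an untransduced sample were chosen after the data were seen. With a cut of 0.1 on both scores, the share called S or G2/M was 46.2% in untransduced cells, 4.79% at day 0, 33.6% at day 7, 3.14% at day 14 and 24.003% at day 21. The S shares were then 12.0%, 2.18%, 5.82%, 1.62% and 4.36%, and the G2/M shares that moved beyond their intervals were 27.7% at day 7, 1.52% at day 14 and 19.6% at day 21. The differences from untransduced cells in the share called S or G2/M became -12.6 points at day 7, -43.1 at day 14 and -22.2 at day 21, and day 21 minus day 14 became 20.9 points. S share differences that moved were -10.4 and -7.67 points for days 14 and 21 against untransduced cells and -4.20 for day 14 minus day 7; G2/M differences that moved were -14.5 points for day 21 against untransduced cells and 18.1 for day 21 minus day 14. In all, 22 of 36 results moved with this cut.

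Counting day 0 as control gave 39.9% of control cells called S or G2/M and 24.6% called G2/M. Day 7 minus control then reversed to 5.47 points for S or G2/M and 6.90 for G2/M, and day 21 minus control to 1.91 and 1.41 points, while day 14 minus control stayed negative at -23.7 points. The construction of this control, in which 459 of 1340 cells are day 0 cells, accounts for the change; of 20 results, 9 moved and 7 reversed. Median S score differences from this control were 0.0033 at day 7 and 0.00090 at day 21, both reversed, and -0.024 at day 14; for the G2/M score they were 0.037 at day 7, 0.012 at day 21 (reversed) and -0.010 at day 14.

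With the mean in place of the median, all 24 results moved beyond their intervals, and the score differences kept their direction except that of the G2/M score between day 7 and untransduced cells, whose medians were nearly equal. Those intervals are of medians, and scores with a long upper tail have higher means (untransduced G2/M score: median -0.070, mean 0.201). The count of moved results therefore does not measure stability. Differences of mean S scores were -0.145, -0.080, -0.147 and -0.098 for days 0, 7, 14 and 21 against untransduced cells, 0.065 for day 7 minus day 0, -0.067 for day 14 minus day 7 and 0.048 for day 21 minus day 14. For the G2/M score they were -0.310, -0.107, -0.305, -0.177, 0.204, -0.198 and 0.128 in the same order. Leaving out either untransduced sample moved none of 50 results beyond its interval, but S share differences from untransduced cells depended on it: without the sample of 470 cells they were -4.41, -1.29, -2.42 and 0.641 points for days 0, 7, 14 and 21, and without that of 411 cells -9.11, -5.99, -7.12 and -4.06, and the near-zero median G2/M difference at day 7 became 0.012 and -0.010. Furthermore, leaving out single portions moved 1 of 165, and weighting portions equally moved none of 36. Planned filters on detected genes, mitochondrial percentage and totals, and matching on depth, were not run, because the table has no such column. Depth per cell is unknown here and limits every comparison of scores. No paired analysis was possible because no day has replicate samples with shared numbers.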

Other observations

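The balance of S and G2/M calls depended on the cut. With the deposited cut of 0, S calls were 33.0% of S and G2/M calls in untransduced cells (exact 95% interval 28.8 to 37.5%), 30.4% at day 7 (27.0 to 34.0%) and 37.7% at day 21 (33.6 to 41.8%), with overlap of both days with untransduced cells, and 75.4% at day 0 (63.1 to 85.2%) and 78.4% at day 14 (73.4 to 82.8%). With a cut of 0.25, 292 untransduced cells were called G2/M and 84 S, so that S calls were 22.3% of both (18.2 to 26.9%). The S percentage was 12.9% of 396 such cells at day 7 (9.74 to 16.6%) and 13.3% of 225 at day 21 (9.18 to 18.5%), the day 7 interval lying below that of untransduced cells and the day 21 interval overlapping its lower end. Day 0 and day 14 left only 16 and 29 such cells, with 37.5% (15.2 to 64.6%) and 37.9% (20.7 to 57.7%). With a cut of 0.1, the S percentage was 51.6% at day 14 (38.6 to 64.5%), above 26.0% in untransduced cells (21.8 to 30.6%). At day 0 it was then 45.5% (24.4 to 67.8%), with an interval that overlapped that of untransduced cells. Days 7 and 21 had 17.3% (14.2 to 20.9%) and 18.2% (14.1 to 22.9%) with this cut. Across cells within a group, the S and G2/M scores had a Spearman correlation of 0.713 in untransduced cells, 0.652 at day 7 and 0.553 at day 21, but 0.262 at day 0 and 0.227 at day 14; cells are not independent replicates.

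All tests in this part were chosen after the data were seen. The first pattern is the alternation of the share called S or G2/M, low at days 0 and 14 and high at days 7 and 21. Uneven portions are argued against as the source of the low day 14 share, with a largest range of 6.68 points over portions against a gap of 25.6 points to the nearer high day; day 0 has 1 portion and is not covered. Separate barcoding runs for low and high days stay open, and what the identifier numbers stand for is not given: over the 92 second identifier numbers left after 4 extreme ones, the cell counts of low and high days had a Pearson r of 0.115 (one-sided permutation p = 0.137; Spearman rho 0.093), and the permutation p for a difference of their profiles over all numbers was 0.055. Among the extreme numbers, 84 and 96 together held 0.216% to 0.322% of the cells of every group, where an even spread gives 2.08%. Numbers 12 and 24 held 4.96% and 5.55% of cells at days 0 and 14 and 4.25% and 3.37% at days 7 and 21, with day 14 (4.59 to 6.64%) above day 21 (2.47 to 4.48%). Untransduced cells, with the highest share called S or G2/M, held 6.24% there (4.74 to 8.05%). Shares at these numbers therefore did not follow the share called S or G2/M over all groups. Extremes shared by all groups go with 1 run. They could also appear in separate runs that used the same barcode plates, so they do not decide. No first number was shared between days. Days 0 and 14 held first numbers 3 and 7 to 9, and days 7 and 21 held 4 to 6 and 10 to 12. This also goes with 1 run, but separate runs could have been numbered apart, so it does not decide either. Fewer reads per cell at days 0 and 14 may also lower such scores. This cannot be told apart from a change in the cells because depth is unknown here. The SD of the S score among G1 cells, an indirect measure, was 1.01 times as large at day 14 as at day 7. At days 14, 7 and 0 it was 0.0323, 0.0319 and 0.0332, and for the G2/M score 0.0491, 0.0502 and 0.0458. G1 calls require both scores below 0, which bounds these SDs, so they do not decide on depth. Exchanged labels, culture density, passage and the time since induction stay open and were not tested.

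The second pattern is that S calls at days 0 and 14 (10.7% and 12.7%) were nearly as frequent as at day 7 (13.8%), while G2/M calls were about 9-fold rarer. Both scores being lower by up to 0.1 at days 0 and 14 is argued against as the source of the rare G2/M calls: day 7 cells lowered in this way would still give a G2/M share of 27.7% (25.5 to 30.05%), 7.93-fold above the 3.50% of day 14 (2.73 to 4.40%) and also above the 3.49% of day 0 (2.01 to 5.60%). Day 7 cells with both scores lowered by 0.5 would give 14.8% (13.0 to 16.7%). Lowered by 0.8, they would give 7.00% (5.77 to 8.39%), still above the intervals of days 14 and 0. Equal shifts of up to 0.8 are thus argued against as well. Shifts this large would also have moved the lower end of the scores, where the groups differed little. The 10th percentile of the G2/M score was -0.164 at day 7, -0.178 at day 14 and -0.192 at day 0. The limit of 0.8 therefore adds little to that of 0.1. A change that is not the same in all cells was not tested. For the S share, scores just above the cut are a candidate explanation: with a cut of 0.1 it differed from day 7 by -4.20 points at day 14 (Newcombe 95% interval -5.57 to -2.95), and day 7 lay 3.64 points above day 0 (1.56 to 5.27), so the S shares were near-equal with a cut of 0 and not with a cut of 0.1. Of the S calls, 87.2% at day 14 (82.4 to 91.1%) and 79.6% at day 0 (65.7 to 89.8%) had an S score of at most 0.1, against 31.6% in untransduced cells (24.4 to 39.6%), 57.8% at day 7 (50.8 to 64.6%) and 72.2% at day 21 (65.7 to 78.2%), the last overlapping day 0. These low-scoring calls are the ones that a cut of 0.1 removes, so both sets of values describe the same fact. Of the G2/M calls, 56.5% at day 14 (44.0 to 68.4%) and 4 of 16 at day 0 (25%, 7.27 to 52.4%) had a G2/M score of at most 0.1, against 12.03% at day 7 (9.27 to 15.3%). What lowered the G2/M share stays open, and no biological explanation of this pattern was tested.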
